A study of Rattus norvegicus with 6 samples.

How the data were processed

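Poly(A)-enriched RNA from brain tissue of rats was sequenced in 6 libraries, 3 from animals with experimental autoimmune prostatitis (EAP) and 3 labelled normal. EAP is a model of chronic prostatitis in which rats are injected with prostate protein in Freund's adjuvant, per the labels' design text. The region of the brain, the batch and the number of animals behind a library are not given in the sources used here. The labels give each library a replicate number but do not say whether it is a separate animal, so p-values measure only the spread between these libraries.

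The authors deposited 1 table of raw read counts per Ensembl gene, whole numbers with no normalization, per the file headers. The submitters' processing notes name Trimmomatic 0.39, HISAT2 2.2.1, featureCounts 2.0.3, DESeq2 1.36.0 and the build Rnor_6.0. Their settings, the annotation release and whether reads were counted by strand are not given in the sources used here. Reads shared by overlapping genes or near-identical copies are therefore of uncertain assignment. The table holds 22250 Ensembl gene IDs. All 6 count columns were matched to libraries by name, and 0 other columns held values. No line named a class of unassigned reads.

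The count table does not pair its IDs with gene symbols. The reference gene table used here has 47357 entries, of which 0 carry an Ensembl ID, and 0 of the table's IDs could be matched. No symbol was assigned. Before the data were examined, 44 gene lists were fixed for a set test (pathways of inflammation, neurotransmitters, sex and stress hormones, pain and metabolism, and markers of brain cell types and regions). These lists, a set of genes always to be given, and the part of the naming rule that asks for a symbol could not be applied, so no list result is reported. Coordinates are not used here.

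Counts were tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3), with group as the only term, TMM factors, robust dispersions and the tool's expression filter by group. The filter kept 13155 of the 22250 genes, and the genes left out held 0.0761% of all counts. The test was two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are EAP over normal, and CPM values are counts scaled to library size with TMM factors, computed from the deposited counts. Principal components used log2 CPM with a prior count of 2. Values per library were compared with an exact permutation test, two-sided, which cannot give a p below 0.1 with 3 libraries against 3. The naming rule, fixed before the data were examined, took the 12 largest changes in each direction among genes past the threshold with a mean log2 CPM of at least 1 and no overlap between groups, filling up with the smallest p where fewer than 5 passed. As IDs carry no symbols, at most 2 IDs per direction are printed. For a gene with no count in 1 group, the fold is a lower bound against a floor of 3 counts per library. Sets of genes with counts in 1 group only, or with a fitted fold of 16 or more, were defined after the data were examined.

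Libraries held 12534210 to 14669760 counts, and 3 counts corresponded to 0.205 to 0.235 CPM. Floors cover counting error only, since the reads carry no molecular identifiers. The fits were tested on simulated data: in 5 simulated tables of 13155 genes, 200 genes were changed. Counts were drawn from the real means and library sizes, with dispersions that edgeR estimated per gene from these libraries, which may favour edgeR. At a true fold of 1.5, 2 and 4, edgeR recovered 14.3%, 66.9% and 87.6% of the changed genes, and 9.08% of its calls were false. DESeq2 recovered 21.2%, 73.7% and 90.6%, with 20.2% of its calls false. Genes were drawn independently, with no factor shared by the genes of a library. The shares depend on these settings and on the 200 changed genes, so they are not measured for the real libraries.

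No library was a copy of another within counting noise: the chi-square statistic per degree of freedom between libraries was at least 22.0. This does not show that they come from separate animals; they were analysed as separate samples because the labels list them so. Alternatives fixed before the data were examined were other scaling factors (DESeq2 median ratios, upper quartile, total count), no filter or a filter at 1 CPM in 3 libraries, DESeq2 1.42.0, limma voom (limma 3.58.1), non-robust dispersions, the replicate number as a block, other thresholds and leaving out each library. Alternatives chosen after the data were examined were thinning all libraries to the smallest total, the newer edgeR quasi-likelihood method, leaving out 1 library of each group, and raising levels to the floor for folds of 16 or more.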

Results

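The transcriptome of rat brain tissue was profiled in 3 EAP and 3 normal libraries, to ask how brain expression differs in a model of chronic prostatitis that the study examined for sexual dysfunction. Total counts were 12534210, 13314793 and 13078670 in EAP replicates 1 to 3 and 13654094, 13514840 and 14669760 in normal replicates 1 to 3. EAP libraries averaged 12975891 ± 400312 counts (SD, n = 3) and normal libraries 13946231 ± 630451 counts (SD, n = 3). The groups did not overlap in depth (exact permutation p = 0.1, the smallest this design allows). Between 15387 and 15585 genes had at least 1 count per library, and the 100 most abundant genes took 29.0% to 30.9% of the counts.

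The first principal component held 37.1% of the variance between libraries and placed all 3 EAP libraries on one side of the 3 normal libraries (exact permutation p = 0.1, the smallest possible). EAP replicates 2 and 3 lay close together at -32.6 and -29.1, and normal replicates 1 and 3 lay at 28.7 and 30.2. EAP replicate 1, at -6.59, and normal replicate 2, at 9.38, lay nearer to each other than to the rest of their groups on this axis. Across genes, EAP replicate 1 correlated more closely with normal replicate 2 (Pearson r = 0.975) than with EAP replicates 2 (r = 0.971) and 3 (r = 0.972), while normal replicate 2 correlated most closely with normal replicate 3 (r = 0.978); genes are not independent replicates. The second component held 19.4% and did not separate the groups (exact permutation p = 0.5). On it EAP replicate 1 (27.0) lay beside normal replicate 1 (21.7) and far from normal replicate 2 (-17.1), which lay beside normal replicate 3 (-20.6).

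**Figure D1:**
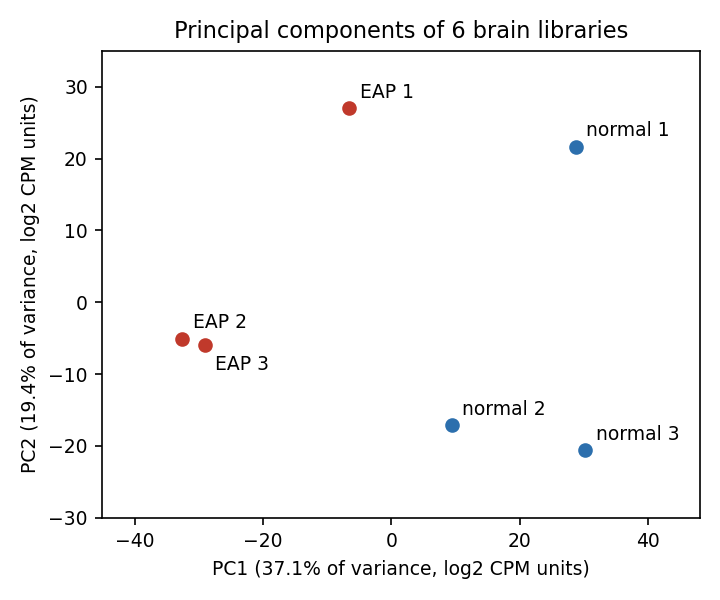
Principal components 1 and 2 of log2 CPM for each of the 6 libraries, in log2 CPM units, with EAP in red and normal in blue. EAP replicates 2 and 3 lie at -32.6 and -29.1 on the first component, while EAP replicate 1 (-6.59) and normal replicate 2 (9.38) lie nearest to its centre.

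A small number of genes passed the test between EAP and normal brain. Of 13155 genes tested, 1 rose and 3 fell in EAP (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.047 for each). The gene that rose, ENSRNOG00000019050, had 53, 46 and 50 counts in the EAP libraries and 0 in each normal library. Its level in EAP was 3.76 ± 0.372 CPM (SD, n = 3), at least 17.1-fold higher than the floor of 3 counts per library in normal brain. ENSRNOG00000012477 fell by 2.56 on the log2 scale (SE 0.306), from 15.0 ± 5.17 CPM in normal to 2.53 ± 0.468 CPM in EAP (SD, n = 3 each). ENSRNOG00000027030 fell by 1.21 (SE 0.144), from 18.4 ± 0.875 to 7.94 ± 0.52 CPM. The remaining gene, the most abundant of the 4, fell by 0.92 (SE 0.113), from 212 ± 23.2 to 112 ± 10.4 CPM. In each of these 4 genes the 3 libraries of 1 group lay above the 3 of the other. No second gene passed in the upward direction; the one with the smallest p under the naming rule, ENSRNOG00000004793, had 101 ± 3.27 CPM in EAP and 72.4 ± 1.68 CPM in normal, a log2 difference of 0.48 with an edgeR adjusted p of 0.183.

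The number of genes called was set by single libraries and by the tool. Leaving out EAP replicate 2, EAP replicate 3 or normal replicate 3 left 0 genes past the edgeR threshold, with 980, 1013 and 965 genes at an unadjusted p under 0.05. Leaving out EAP replicate 1, normal replicate 1 or normal replicate 2 gave 14, 47 and 22 genes. Applied to all 6 libraries, DESeq2 called 187 genes, 23 higher and 164 lower in EAP, with the 4 edgeR genes among them, and limma voom called 1. Of the 164 genes that DESeq2 called lower, 94 were at least 2-fold and 62 at least 4-fold lower by the fitted fold; of the 23 called higher, 13 were at least 2-fold and 5 at least 4-fold higher. The lower genes were thus 87.7% of the DESeq2 calls, and 74.4% with total-count scaling. Without EAP replicate 1 or normal replicate 2, DESeq2 called 397 and 425 genes; without EAP replicate 2, EAP replicate 3, normal replicate 1 or normal replicate 3 it called 88, 96, 132 and 62.

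Below the adjusted threshold, 1464 genes had an unadjusted edgeR p under 0.05, against 658 that this level would give by chance with independent genes. Of these, 635 were higher and 829 lower in EAP; with total-count scaling the split was 957 higher and 537 lower, and with upper-quartile scaling 939 higher and 597 lower. Scaling shifts all genes of a library alike, so these splits are not read as a direction. The 3 libraries of 1 group lay above the 3 of the other for 1104 genes higher and 1106 genes lower in EAP, together 16.8% of the genes tested, where chance gives 10% on average. Genes are not independent, so a single split can depart from 10% by chance, and the share in other splits was not computed.

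**Figure D2:**
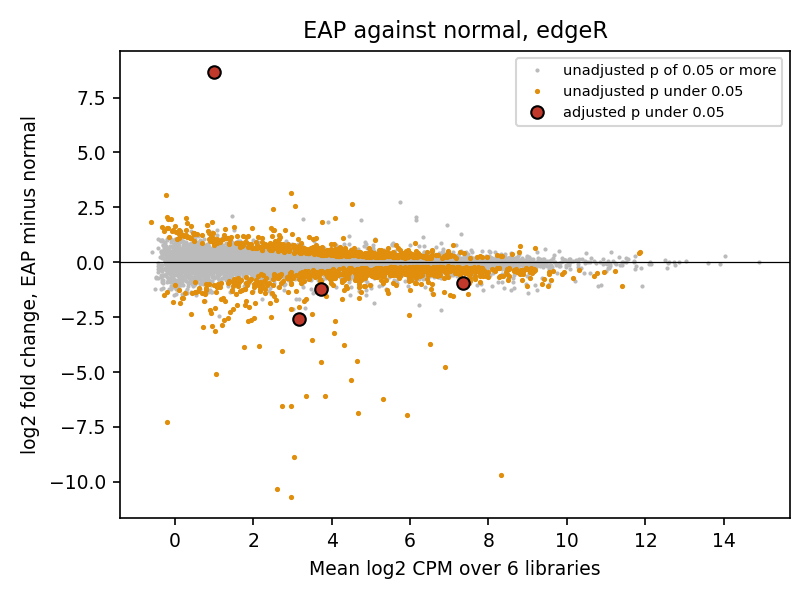
The log2 fold change of EAP over normal for each of 13155 genes against its mean log2 CPM over 6 libraries, from edgeR. Grey points have an unadjusted p of 0.05 or more, orange points an unadjusted p under 0.05, and the 4 outlined red points an adjusted p under 0.05 (1 higher and 3 lower).

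Most of the large differences were decreases in EAP. Among genes with an unadjusted edgeR p under 0.05, 18 had a fitted fold of 16 or more with lower levels in EAP and 1, ENSRNOG00000019050, with higher levels; at a fitted fold of 4 or more, 47 were lower and 8 higher. With EAP levels raised to a floor of 3 counts per library, 17 of the 18 stayed at 16-fold or more, and the remaining one, at 0 in EAP, was at least 6.23-fold lower. None of the 18 passed the adjusted edgeR test (adjusted p 0.183 to 0.389), while DESeq2 called all 18. In all 18, each normal library lay above each EAP library, which the expression filter favours for genes near 0 in EAP. Together they made up 0.00136% to 0.00247% of the counts of the EAP libraries. Their share was 0.0174% in normal replicate 1, 0.173% in normal replicate 2 and 0.22% in normal replicate 3. Their summed level was 17.6 ± 5.8 CPM in EAP and 1371 ± 1054 CPM in normal (SD, n = 3 each, exact permutation p = 0.1, the smallest possible). This separation follows from the choice of the genes, so the p-value adds no support. The most abundant of them had 11, 9 and 11 counts in the EAP libraries and 476, 10018 and 16846 counts in normal replicates 1, 2 and 3. In 16 of the 18, normal replicate 1 had the lowest level of the 3 normal libraries. By the fitted fold, the count of such genes was 41, 29 and 28 without EAP replicates 1, 2 and 3 (1, 1 and 2 higher). It was 36 without normal replicate 1 (4 higher) and 71 with no filter on low counts (17 higher). DESeq2 gave 55 lower and 5 higher. With the lower group raised to the floor these counts were 22, 15 and 14 (1, 1 and 2 higher), 25 (2 higher) and 20 (2 higher). For DESeq2 the count was then 20 (2 higher).

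**Figure D3:**
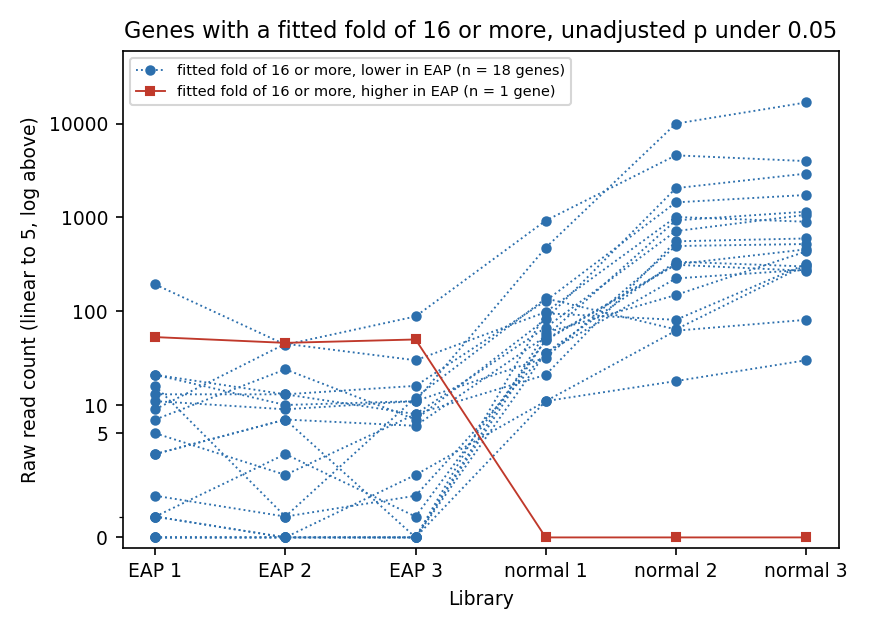
Raw read counts, on an axis linear to 5 and logarithmic above, of the 18 genes with a fitted fold of 16 or more and lower levels in EAP (blue circles, dotted lines) and the 1 such gene with higher levels (red squares), each line joining 1 gene's counts over the 6 libraries. The most abundant lower gene has 9 to 11 counts in EAP and 476 to 16846 in normal libraries, and the higher gene has 46 to 53 in EAP and 0 in normal.

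Some genes had reads in 1 group only. With a minimum of 5 counts in each library of the other group, 7 genes had no count in any EAP library and 1 gene, ENSRNOG00000019050, had none in any normal library. The 7 genes had 5 to 434 counts per normal library, which places them at least 2.02-fold to at least 66.5-fold above the floor of 3 counts per library in EAP. Of the 18 genes described above, 3 belong to this group, with lower bounds of 66.5-fold, 51.6-fold and 6.23-fold. DESeq2 called 6 of the 7. The edgeR filter kept 3 of the 7, and edgeR called 0 of these, with 3 at an unadjusted p under 0.05. With a minimum of 3 counts the numbers were 12 and 2, and with a minimum of 10 they were 4 and 1.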

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

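The thinned libraries, the newer edgeR method, the floor for folds of 16 or more and the fits without 1 library of each group were chosen after the result was seen. The count of 4 genes from edgeR rested on values close to the threshold. It was 4 with DESeq2's size factors in edgeR, with a filter at 1 CPM and with libraries thinned to 1 depth, in each case the same 4 genes, and 5 at an adjusted p under 0.10. It fell to 0 with upper-quartile factors, with non-robust dispersions and with the newer edgeR quasi-likelihood method (1536, 1512 and 1484 genes at an unadjusted p under 0.05), and to 1 with total-count scaling and with limma voom. It rose to 7 with no filter on low counts and to 187 with DESeq2, and 229 genes had an unadjusted p under 0.05 with a 2-fold change. Summed over the 5 simulated tables, edgeR made 617 calls (9.08% false) and DESeq2 773 (20.2% false). In proportion this gap is far smaller than between 4 and 187 genes in the real table. The simulation had 200 changed genes per table, independent genes and dispersions from edgeR, and the cause of the real gap was not tested. Leaving out 1 library, or 1 of each group, gave 0 to 333 genes. With the replicate block, edgeR called 80 genes, 10 higher and 70 lower, including the 4. The replicate numbers share no stated origin. Deviations from the group means correlated at 0.0515 to 0.0718 between same-numbered libraries, under the 0.1 taken to mark pairs. All 6 libraries correlated best with their own number, a hint from the data only. Deviations sum to 0 within a group, so these 6 matches are not separate observations. Named genes have no overlap between groups by rule, so a change of direction was hardly possible, and none occurred in 17 alternatives. ENSRNOG00000019050 stayed past the threshold in 11 of them, ENSRNOG00000027030 in 9 and ENSRNOG00000012477 in 8, and ENSRNOG00000004793 passed only with DESeq2 (adjusted p = 0.0025, range over the alternatives up to 0.618). The number of genes with an unadjusted p under 0.05 was 965 to 1884 when 1 library was left out. The set tests on 44 gene lists and their alternatives were not run, since no ID could be matched to a symbol. With 3 libraries per group at this depth and spread, changes of 1.5-fold were mostly missed on simulated data (14.3% recovered by edgeR). A gene outside the calls is therefore not shown to be unchanged.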

Other observations

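The tests of exchanged labels, of the normal libraries behind the 16-fold set, of a single source of RNA, of EAP RNA in normal replicate 2, and the counts over other splits were chosen after the result was seen; those of normal RNA in EAP replicate 1, depth, scaling and shared variation were set before their results.

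The 10 ways to split the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 4 genes with edgeR and the highest other 1, and 1 split, the real one, reached that count. For genes with an unadjusted p under 0.05 the real split gave 1464 and the highest other 1247. For genes with a fitted fold of 16 or more it gave 19 against 4, and for genes with counts in 1 group only 8 against 1. Both kinds of genes were defined after the data were examined in the real grouping, which favours the real split. With DESeq2, 2 splits gave as many genes as the real one: the real split gave 187, and the split that exchanges EAP replicate 1 and normal replicate 2 gave 240. That split keeps the other 4 libraries in their own groups, so the group and an unlabelled factor that also parts those 4 both stay open behind it.

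EAP replicate 1 and normal replicate 2 lay between the groups on the first principal component. With both left out, edgeR called 333 genes in the other 4 libraries, against 0 to 73 for the other 8 pairs left out. On the 200 genes with the smallest p in those 4 libraries, with 0 set at the normal and 1 at the EAP mean, EAP replicate 1 lay at 0.409 (95% interval over resampled genes 0.326 to 0.503) and normal replicate 2 at 0.481 (0.396 to 0.575), where a library unrelated to the axis lies at 0.5. Over all 9 pairs left out, the EAP library lay above the normal one in 8, with means of 0.781 and 0.324. The pairs reuse the same 6 libraries, so they are not separate observations. Mean positions were 0.543, 0.945 and 0.854 for EAP replicates 1 to 3. For normal replicates 1 to 3 they were 0.505, 0.485 and -0.0172. EAP replicate 1 ranged from 0.409 to 0.789, and normal replicate 1 (0.435 to 0.548) lay as far between the groups as normal replicate 2 (0.453 to 0.52). These positions do not decide whether the 2 labels were exchanged. Whether the labels were exchanged was also examined in 7 genes. They were at 0 in EAP replicates 2 and 3 and at 10 or more in normal replicates 1 and 3. Together they had 626 counts in normal replicate 2 and 7 in EAP replicate 1, against 259 and 1179 in normal replicates 1 and 3. Of the 7, 6 were higher in normal replicate 2 than in EAP replicate 1. However, 4 of the 7 belong to the 18 genes with a fitted fold of 16 or more and lower levels in EAP. These 4 had 18, 338, 149 and 81 counts in normal replicate 2, and may mark a tissue held in unequal amounts. The rest had 32, 4 and 4. The counts thus argue against an exchange only if the genes follow EAP status, which was not tested. Normal RNA mixed into EAP replicate 1 in the share given by its position would have put about 380.2 counts of the 7 genes there. The position is on a log2 scale, so this count may be too high. The 7 counts found also lie under 26.9, the lower Poisson bound for 10% of it. This argues against mixed-in RNA like that of normal replicates 1 and 3, but not against normal RNA low in these 7 genes. EAP RNA in normal replicate 2 stays open: 1 gene at 0 in normal replicates 1 and 3 and at 10 or more in EAP replicates 2 and 3 had 0 counts there, against 23.2 implied by its position, and 4 genes at 5 or more had 9 against 31.9, too few genes to decide. Thinning to 1 depth left the positions at 0.407 and 0.496, which argues against depth; a graded response to EAP, a difference in the tissue taken and an unlabelled batch stay open and untested.

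The 18 genes with a fitted fold of 16 or more and lower levels in EAP may mark a tissue or cell population that the normal libraries hold in unequal amounts, or genes that EAP lowers; without gene names the choice between these stays open. Their direction does not rest on normal replicates 2 and 3 alone. Of 36 genes filtered and chosen without normal replicate 1, 35 (97.2%, 95% binomial interval 85.5% to 99.9%, with genes taken as independent) lay above all EAP libraries in normal replicate 1. The median of the 36 genes there was 2.07 above EAP on the log2 scale, short of 16-fold. The size of the folds thus rests more on normal replicates 2 and 3. When each EAP library was held out in turn from the same choice, normal replicate 1 was among the 3 low libraries. Then 13.6%, 10% and 0% of 22, 20 and 19 genes were highest in the library held out (highest upper bound 34.9%). To be so, a gene had to exceed normal replicate 1, itself above EAP in 35 of the 36 genes. These shares therefore largely restate the 97.2% and add no separate support. A single source of RNA in a fixed proportion would give every gene the same ratio of normal replicate 3 to normal replicate 1, once the EAP level is subtracted from both. With the EAP level subtracted, the ratio ran from 2.05 to 36.5 with a median of 7.9. Its SD on the log2 scale was 1.3 (interval over resampled genes 0.961 to 1.53), against a median of 0.503 and an upper limit of 1.12 for the middle 95% of random lists of like expression. Subtraction can widen this spread in genes where normal replicate 1 lies near EAP. The interval lies above the median but spans the upper limit, so the test does not decide and 1 source is not excluded. Depth is argued against for the related genes with no count in EAP, since 6 of 7 remained after thinning.

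The excess of lower genes among the DESeq2 calls may come in part from 1 factor shared by many genes, such as tissue make-up. Within groups, the first axis of the 146 lower genes also tested in edgeR held 44.3% of their deviations from the group means. For 1000 random lists matched on expression the median was 33.61% and the upper limit of the middle 95% was 38%. For the 23 higher genes the share was 38.79%, with no limit from random lists. A shared axis is thus not shown to be particular to the lower genes. The lists were not matched on variance, and the 146 include the 18 genes with a fitted fold of 16 or more. A part of the 146 may thus carry this axis. A coordinated response of the lower genes would give the same result, so it stays open. Scaling is not excluded as a contributor, since the share of lower genes fell from 87.7% to 74.36% with total-count scaling, just under the 75% set as the limit.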
